A study of Homo sapiens with 6 samples.

How the data were processed

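Polyadenylated RNA of A375 cells was sequenced in 6 samples, 3 treated with DMSO and 3 with CuB for 6 h. Per the labels' protocols, libraries were made from 1 µg of total RNA with a TruSeq RNA kit, which does not mark strand. The deposited table holds FPKM (fragments scaled by gene length and library size) for 58735 genes, as made by the authors, with a gene identifier, symbol, coordinates and length. The genome build was GRCh38, per the submitters' processing notes. The aligner, the counting tool and the scaling behind the FPKM values are not given in the sources used here. All 58735 gene identifiers and coordinates were the same as in GENCODE 29, which was used for GC content and 3' UTRs. Columns were assigned to samples by the names in the labels, and 0 columns of sample values were left unused. Replicate numbers come from the labels.

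Each FPKM value was converted back to fragments through the step between low values and the gene length in the table. In each library 100% of values above 0 came out whole within 0.01 of a fragment. The sources do not say whether a fragment is a read or a read pair. The totals were 14845976, 15797757 and 15116550 fragments for DMSO and 15502971, 16072462 and 16137093 for CuB (exact two-sided permutation p = 0.2, adjusted p = 0.2). The library size implied by the FPKM values was 1.034, 1.036 and 1.033 times the fragment total for DMSO and 0.914, 0.9256 and 0.9265 times for CuB. These implied sizes followed median-of-ratios size factors computed over 19223 genes with a fragment in every library, within a range of 0.87%. FPKM as deposited was therefore not scaled to fragment totals, which is why equal fragment totals were added to the scalings set beforehand.

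Tests were run in R 4.3.3 with limma 3.58.1 and statmod 1.5.0. The table holds no raw count column, so count tests on raw counts, meant for a table that holds them, were not run. Values were tested as log2(FPKM + 1) for the 13273 genes with a mean over all 6 samples of at least 1 FPKM. A linear model of the 2 groups without a replicate block was fitted with limma's moderated test and an intensity trend, with 4 residual degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method over all tested genes at a threshold of 0.05. A fold threshold of 2 was applied as a second count. Gene lists with at least 3 tested members were compared by camera at a preset correlation of 0.01, adjusted over the 30 lists, and members were also adjusted over the list alone. All 681 list members were found in the table. Library measures, 6 in all, were compared by exact two-sided permutation tests, for which 0.1 is the smallest p that 3 against 3 can give. Ratios of fragments have exact 95% intervals, and a gene with 0 fragments in a group was set against a floor of 3 fragments over the group. GC content was known for 13265 tested genes (99.94%). Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.

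The groups, the test, the filter, the 33 gene lists and the rule for named genes were chosen before the data were examined. The rule took the genes of the pathway in the series title (STAT3, EIF2S1, EIF2AK3, ATF4, ERN1, XBP1 and DDIT3) and the 10 largest rises and 10 largest falls among genes at an adjusted p under 0.05 with all 3 CuB values on one side of the 3 DMSO values, leaving out names made of an accession or clone name. It also took from 1 to 4 of the 4 largest passing members of each list, or the 2 members with the highest mean where fewer than 2 passed. Other named genes were chosen after their values were seen. Some results for single genes are not reported here.

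Other settings, also fixed beforehand, were pseudocounts of 0.1 and 0.5, no filter, a minimum mean of 5 FPKM, each sample rescaled to the same sum (TPM), median of ratios, quantile normalization, limma without the trend, limma with robust hyperparameters, the replicate number as a block, each library left out in turn, camera with an estimated correlation, and fry. Settings chosen after seeing the data were limma-voom on the recovered fragments, equal fragment totals, a GC correction that removed a lowess curve (span 0.3) on transcript GC content from each library, and the GC correction with the replicate block or with an estimated correlation. The leave-one-out fits keep 2 libraries in one group.

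The limma and camera steps were tested on simulated data with the real genes and library sizes, for CuB against DMSO. In 20 runs of 13522 tested genes on average, with 200 changed genes per run, the share of changed genes recovered was 29.4% at 1.5-fold, 82.3% at 2-fold and 98.3% at 4-fold. Of all calls 7.79% were false, above the nominal 5%. A list raised 1.5-fold was called in 20 of 20 runs, and 2 of 580 tests of other lists were called. Each gene was drawn independently with the same dispersion of 0.012. The simulation thus held neither correlation between genes nor the GC differences between libraries. Its share of false list calls therefore does not measure that of the real libraries.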

Results

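Polyadenylated RNA was sequenced from A375 cells, an established human melanoma line with an activating BRAF mutation, after 6 h with the solvent DMSO or with CuB. The series title spells CuB out as cucurbitacin B, a triterpenoid of the gourd family. The labels give 3 libraries for each of the 2 groups. They give the dose of CuB as 0.2 µM in the protocol and as 100 nM in the library names, so the dose is uncertain. Expression was given in FPKM for 58735 genes. Every value was a whole number of fragments within 0.01 of a fragment, which gave the depth of each library. The DMSO libraries held 14845976, 15797757 and 15116550 fragments assigned to genes, and the CuB libraries 15502971, 16072462 and 16137093. Nothing in the labels says that the replicates were separate cultures, so the p-values measure the spread between these samples, which may be technical. Replicates differed by more than sampling noise in each pair, with a chi-square per degree of freedom from 2.8 to 24.3 across genes. No pair was therefore treated as 1 library.

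The title of the series names reactive oxygen species, STAT3 and 2 arms of the endoplasmic reticulum stress response, eIF2α-ATF4 and IRE1-XBP1, in immunogenic cell death. The comparison of CuB with DMSO asked which of these genes, and which others, differed in mRNA level after 6 h. mRNA of the stress transcription factors was higher with CuB. DDIT3, which encodes the pro-apoptotic factor CHOP, rose from 3.54 ± 0.813 to 58.0 ± 5.62 FPKM (SD, n = 3 per group here and below), 16.4-fold. XBP1, the transcription factor activated by IRE1, rose from 15.6 ± 0.451 to 65.2 ± 2.89 FPKM, 4.19-fold. ERN1, which encodes IRE1, rose from 1.37 ± 0.139 to 4.97 ± 0.33 FPKM, and ATF4, the factor translated when eIF2α is phosphorylated, rose from 99.3 ± 6.77 to 216.5 ± 3.01 FPKM. STAT3 was at 23.0 ± 1.01 FPKM with DMSO and 21.7 ± 0.283 FPKM with CuB, and this difference did not pass the test.

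The limma adjusted p was 8.15e-06 for DDIT3, 6.93e-06 for XBP1, 0.000116 for ERN1 and 6.75e-05 for ATF4. In each of these genes all 3 CuB values lay above all 3 DMSO values. The groups also did not overlap in EIF2S1 and EIF2AK3, higher with CuB, or in STAT3, lower with CuB. Such separation was found in 51.5% of all tested genes. STAT3 had a log2 fold change of -0.08 (SE 0.0729, adjusted p = 0.427). It passed as lower under quantile normalization, at a log2 fold change of -0.26, after division by equal fragment totals, at -0.24, and after a correction for GC content, at -0.13, but not when the replicate block was added to that correction (adjusted p = 0.0773). EIF2S1, which encodes eIF2α, was at 25.7 ± 2.15 and 31.3 ± 2.05 FPKM (adjusted p = 0.0504). It passed with the GC correction (adjusted p = 0.00281), with voom on the recovered fragments (0.0428) and with genes of at least 5 FPKM (0.0456). EIF2AK3, which encodes the eIF2α kinase PERK, was at 3.52 ± 0.585 and 4.38 ± 0.224 FPKM (adjusted p = 0.119), and passed with the GC correction (0.0397) but not with that correction and the replicate block (0.076). The eIF2α phosphorylation and XBP1 splicing that the title refers to cannot be read from gene-level values.

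On GRCh38, STAT3 (ENSG00000168610) lies on chromosome 17 from 42313324 to 42388568 and ERN1 (ENSG00000178607) on chromosome 17 from 64039142 to 64130819. ATF4 (ENSG00000128272) lies on chromosome 22 from 39519695 to 39522685 and XBP1 (ENSG00000100219) on chromosome 22 from 28794555 to 28800597. DDIT3 (ENSG00000175197) lies on chromosome 12 from 57516588 to 57521737, where it overlaps MARS and MBD6 on the opposite strand. EIF2S1 (ENSG00000134001), on chromosome 14 from 67359997 to 67386516, overlaps ATP6V1D on the opposite strand. The library kit does not mark strand, so fragments from shared positions cannot be assigned to a strand.

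Across 13273 genes with a mean of at least 1 FPKM, 10865 of them protein-coding, 5118 (38.6%) changed at an adjusted p under 0.05, 3046 up and 2072 down. Of these, 961 changed at least 2-fold, 647 up and 314 down, and 132 rose and 23 fell at least 4-fold. These folds are on the log2(FPKM + 1) scale, which understates the change of genes with low values. At an unadjusted p under 0.05 there were 6422 genes. The values of the groups did not overlap for 6831 genes (51.5%), where chance gives 10%. The split of the calls depended on the scaling. Of the changed genes, 59.5% were higher with CuB as deposited, 46.7% with each library rescaled to the same sum, 47.2% after quantile normalization and 39.3% with equal fragment totals. Equal fragment totals shifted the median log2 fold change of all tested genes by -0.139, from 0.0548 to -0.0844. Leaving out CuB replicate 2 gave 3262 changed genes, 1965 up and 1297 down, and leaving out DMSO replicate 1 gave 1359 down. Within each group the libraries differed along the GC content of the transcripts, DMSO replicate 2 apart from the other DMSO libraries, and without that library 5755 genes changed.

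**Figure D1:**
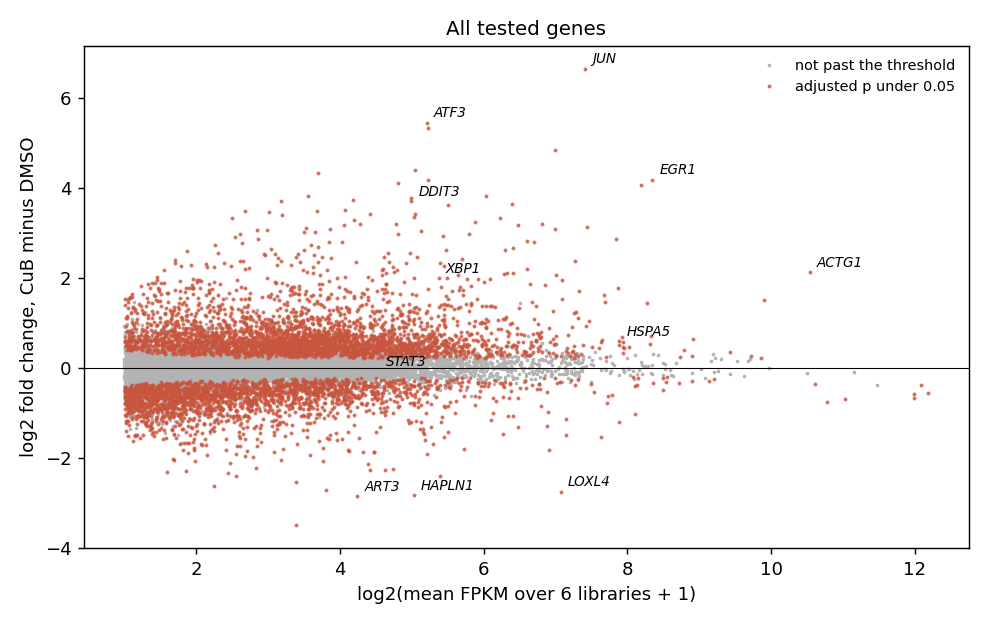
Log2 fold change of each of the 13273 tested genes (vertical axis, CuB minus DMSO) against its mean expression (horizontal axis, log2 of the mean FPKM over 6 libraries plus 1). The 5118 genes at an adjusted p under 0.05 are coloured, JUN is the highest point at 6.66, and STAT3 lies near 0 at -0.08.

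The 10 largest rises were led by immediate early transcription factors. JUN, a subunit of AP-1, rose from 2.37 ± 0.85 to 334.0 ± 38.8 FPKM, 141-fold (log2 fold change 6.66, adjusted p = 3.82e-06). It lies on chromosome 1 from 58780788 to 58784327 (ENSG00000177606). ATF3, a stress-induced bZIP factor, rose from 0.645 ± 0.098 to 71.1 ± 5.37 FPKM and EGR2, a zinc finger factor, from 0.794 ± 0.154 to 71.9 ± 1.13 FPKM. NR4A3, an orphan nuclear receptor, rose from 0.207 ± 0.0458 to 23.7 ± 4.01 FPKM, and EGR1 from 33.0 ± 3.7 to 616.0 ± 32.7 FPKM. Secreted factors were also among the 10. IL24, a cytokine of the IL-10 family, rose 32.9-fold to 244.1 ± 25.6 FPKM, IL11, a cytokine of the IL-6 family, rose 24.1-fold to 69.6 ± 5.25 FPKM, and CXCL8, a neutrophil chemokine, rose 17.2-fold to 551.5 ± 150 FPKM. The others were TNFAIP3, a feedback inhibitor of NF-kB (31.1-fold), and CHAC1, a glutathione-degrading enzyme induced by ATF4 (24.8-fold).

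The 10 largest falls included extracellular and signalling genes. LOXL4, which encodes a lysyl oxidase of the extracellular matrix, fell from 233.2 ± 18.5 to 33.8 ± 2.31 FPKM (log2 fold change -2.75, adjusted p = 4.34e-06). It lies on chromosome 10 from 98247690 to 98268250 (ENSG00000138131) and shares positions with the antisense gene AL139241.1. HAPLN1, a hyaluronan link protein, went from 56.1 ± 7.81 to 7.002 ± 0.931 FPKM, and ART3, an ADP-ribosyltransferase family member, from 32.2 ± 3.76 to 3.62 ± 0.544 FPKM. TRIB2, a pseudokinase, went from 69.4 ± 1.01 to 12.4 ± 0.651 FPKM. SOD3, the extracellular superoxide dismutase, DEPTOR, an inhibitor of mTOR, and MGP, a matrix protein, fell by 2.53, 2.40 and 2.32 on the log2 scale. The other 3 were very short genes with few fragments. MIR3125, inside TRIB2 on the same strand, had 27 fragments with DMSO and 1 with CuB, a ratio of 25.1 (95% interval 4.14 to 1030). MIR3186, opposite BAHCC1, had 20 and 1, a ratio of 18.6 (2.97 to 771). IGHVII-40-1, an immunoglobulin pseudogene, had 11 and 0, at least 3.41-fold lower against a floor of 3 fragments over the group. These intervals and floors cover counting error only.

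**Figure D2:**
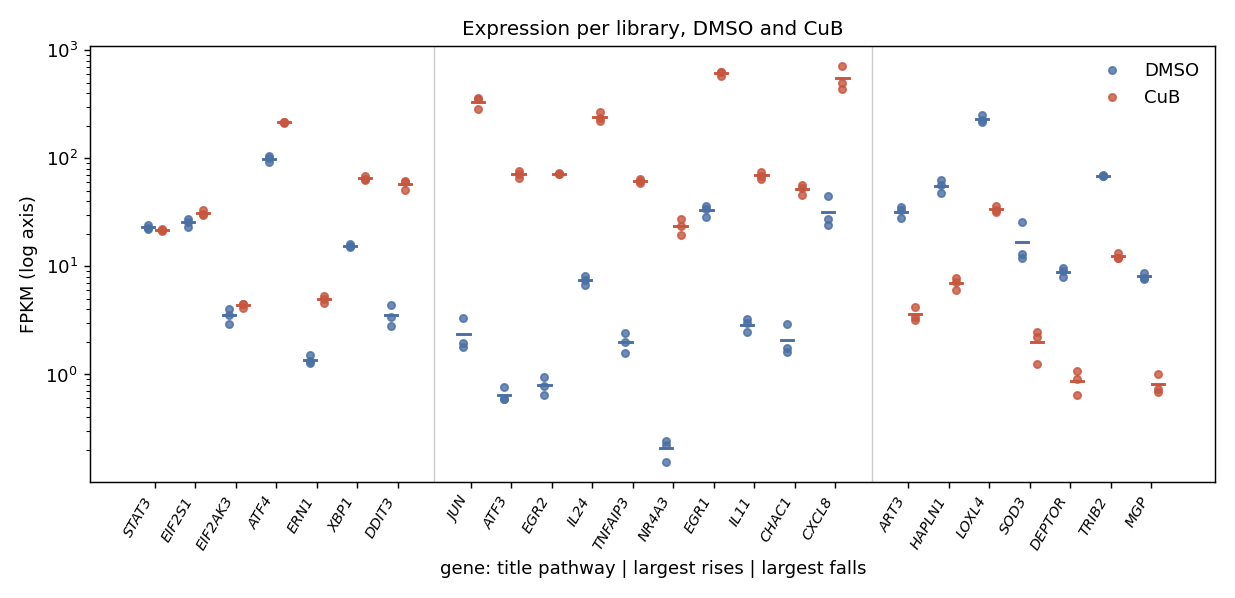
FPKM on a log axis for the 7 genes of the title pathway, the 10 largest rises and 7 of the largest falls, leaving out the 3 shortest genes. Points are single libraries, 3 per group, and bars are group means. JUN has means of 2.37 FPKM with DMSO and 334.0 FPKM with CuB, while the means of STAT3 are 23.0 and 21.7 FPKM.

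Gene lists fixed before the data were examined were then compared with camera, at a preset correlation between genes of 0.01. Of 33 lists 30 could be tested, and 16 passed at an adjusted p under 0.05, 13 up and 3 down. With a correlation estimated from the 6 libraries, 0 of the 30 passed with camera and 11 had an unadjusted p under 0.05. The calls therefore rest on using the preset option. The size of the correlation alone did not account for the loss, so the p-values of this option do not measure correlation between genes alone. YAP and TEAD targets, apoptosis regulators and cholesterol synthesis genes had estimates of -0.0306, -0.0336 and -0.0042, under 0.01, and also lost the call. So did p53 targets (-0.00698) and genes of the melanoma invasive state (-0.0511). The remaining called lists had estimates above 0.01, up to 0.485 for the replication-dependent histones. Another limma test, fry, which asks whether the genes of a list move on balance one way and does not compare them with other genes, gave 24 lists. Members named only as the few exceptions within a list were chosen after their values were seen. Without the filter on low values SRPRB, HSPA1A, HLA-E, HLA-B, LRP1, LYZ, RPL7A, MT-ND4L and MT-ATP6, described with their lists, did not pass (adjusted p from 0.0503 to 0.235). Nor did KRT14 (0.0946), KRT8 (0.0668) and NDUFB5 (0.0768).

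**Figure D3:**
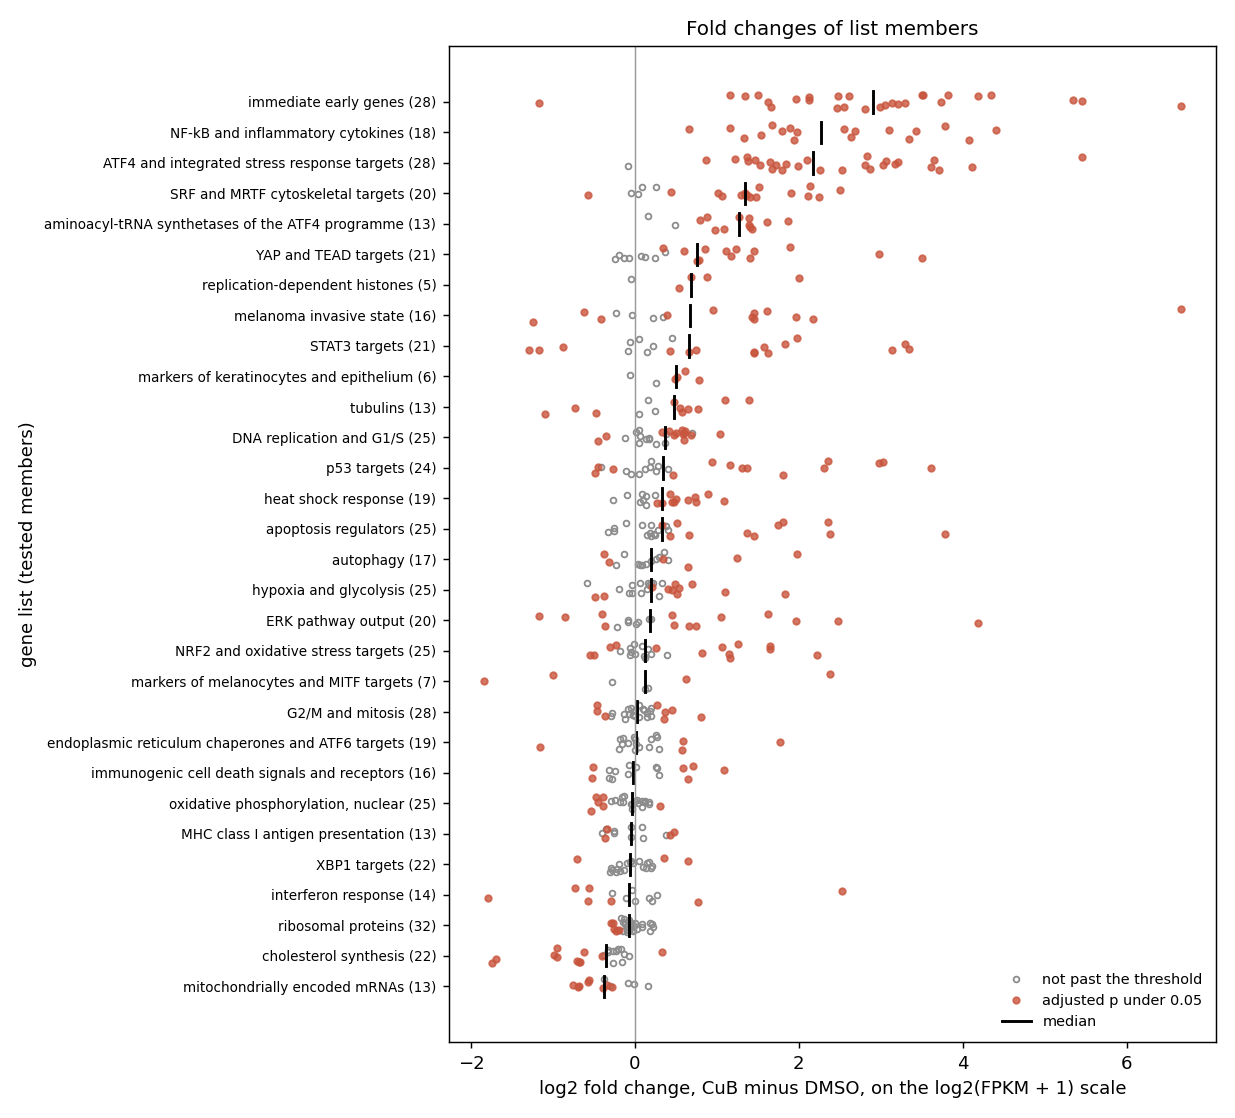
Log2 fold changes (horizontal axis, CuB minus DMSO) of the members of the 30 tested lists (vertical axis, tested members in parentheses), ordered by median. Filled points are genes at an adjusted p under 0.05 and black bars are medians, which run from 2.90 for immediate early genes to -0.378 for mitochondrially encoded mRNAs; MT-ATP6, a member of the latter, is at 0.03 under quantile normalization.

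Targets of ATF4 and the integrated stress response rose together. Of 28 tested members 27 rose and 0 fell, the same counts when adjusted over the list alone, with a median log2 fold change of 2.18. After ATF3, CHAC1 and DDIT3 the next largest was PPP1R15A, the phosphatase subunit that reverses eIF2α phosphorylation, from 11.6 ± 3.02 to 155.0 ± 20.8 FPKM. CCPG1, a receptor of reticulum autophagy, did not pass, with a log2 fold change of -0.08. The camera adjusted p was 4.79e-18, and adjusted p = 0.0853 with an estimated correlation. Of 13 aminoacyl-tRNA synthetases of the same programme 11 rose, or 12 adjusted over the list alone, with GARS at 1.87, YARS at 1.61, WARS at 1.43 and SARS at 1.41 on the log2 scale (adjusted p = 7.45e-08; adjusted p = 0.105 with an estimated correlation).

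XBP1 targets gave another count. Of 22 members 2 rose, SEC24D, a coat protein of vesicles leaving the reticulum (0.65), and SRPRB, a signal recognition receptor subunit (0.36), and KDELR3, a retrieval receptor, fell by 0.70. The other 19 did not pass, and adjusted over the list alone 1 rose and 1 fell (median -0.0571, adjusted p = 0.391). SRPRB did not pass under any of 4 rescalings (adjusted p from 0.0624 to 0.181), nor without DMSO replicate 1, 2 or 3 or CuB replicate 1 or 2 (adjusted p from 0.0516 to 0.11), nor with the replicate block (0.0581). Under equal fragment totals the same list had 1 member up and 7 down. Of 19 chaperones of the reticulum and ATF6 targets 3 rose and 1 fell, with the same counts adjusted over the list alone (median 0.0165 as deposited and from -0.129 to -0.0509 under the 4 rescalings, adjusted p = 0.671). The 3 were HERPUD1, a factor of reticulum-associated degradation (1.77), HSPA5, the chaperone BiP (187.4 ± 2.19 to 283.1 ± 4.16 FPKM), and SELENOS (0.58), while ERO1B, an oxidase of disulfide formation, fell by 1.16. The mean log2 level of the ATF4 list minus that of the XBP1 targets moved by 2.42 between the groups (95% interval 2.03 to 2.81; exact permutation p = 0.1, two-sided, the smallest that 3 against 3 can give).

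Targets of STAT3 moved both ways. Of 21 tested members 12 rose and 3 fell, or 13 and 3 adjusted over the list alone (median 0.658, adjusted p = 0.00134; adjusted p = 0.135 with an estimated correlation). LIF, a cytokine of the IL-6 family, rose from 12.4 ± 1.77 to 134.9 ± 7.64 FPKM, FOS, a subunit of AP-1, by 3.29 on the log2 scale, JUNB by 3.14 and ICAM1, an adhesion molecule, by 1.98. Of the 12 that rose 9 are also in another list, and the other 3 were SOCS3, the feedback inhibitor of cytokine signalling (1.63), BCL3 (1.57) and PIM1 (0.66). The 3 that fell were A2M, a protease inhibitor (-1.29), MYC, a growth-promoting transcription factor (-1.17), and OSMR, the oncostatin M receptor (-0.87).

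Oxidative stress genes were mixed. Of 25 NRF2 and oxidative stress targets 9 rose and 4 fell, the same adjusted over the list alone, and the list did not pass (adjusted p = 0.195); its median was 0.128 as deposited but -0.0211 after quantile normalization and -0.0177 with equal fragment totals. HMOX1, heme oxygenase, rose from 1.35 ± 0.112 to 9.98 ± 0.444 FPKM, SLC7A11, the cystine transporter, from 12.8 ± 2.09 to 42.1 ± 4.05 FPKM, OSGIN1 by 1.65 on the log2 scale and FTH1, ferritin heavy chain, by 1.26. Of 19 heat shock genes 11 rose and 0 fell, or 11 and 1 adjusted over the list alone (median 0.332, adjusted p = 0.00824; adjusted p = 0.164 with an estimated correlation), with DNAJB1, a co-chaperone of HSP70, at 0.90 and CHORDC1 at 0.73. The list did not pass after quantile normalization (adjusted p = 0.117) or among genes of at least 5 FPKM (0.055).

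Genes of immunogenic cell death and of class I antigen presentation moved both ways, and neither list passed. Of 16 tested signals and receptors of immunogenic cell death 4 rose and 2 fell, or 5 and 2 adjusted over the list alone (adjusted p = 0.84). The median was -0.0235 while the mean was 0.0951 and the test pointed up. PANX1, the channel that releases ATP, rose from 11.5 ± 0.713 to 19.4 ± 0.708 FPKM, HSP90AA1 from 376.7 ± 41 to 586.5 ± 22.8 FPKM, and HSPA5 and HSPA1A were the other 2. HSPA1A, the inducible HSP70 gene, shares near-identical sequence with HSPA1B and did not pass without DMSO replicate 1 (adjusted p = 0.0542) or CuB replicate 2 (0.056). CD47, which inhibits phagocytosis, and LRP1, a receptor for calreticulin, fell by 0.52 and 0.51, and neither passed without DMSO replicate 1 (adjusted p = 0.0594 and 0.0715) or CuB replicate 2 (0.0642 and 0.0549). CD47 also missed the threshold without DMSO replicate 3 (0.0512) or CuB replicate 3 (0.0542), and LRP1 without CuB replicate 1 (0.0594). CALR, which encodes calreticulin, was at 246.3 ± 24.2 and 301.1 ± 24.7 FPKM (adjusted p = 0.0503), and passed with the GC correction (0.00374), with voom (0.0343), among genes of at least 5 FPKM (0.047), with a pseudocount of 0.1 (0.0491) and without DMSO replicate 2 (0.014) or CuB replicate 1 (0.0401). HMGB1, a nuclear protein released from dying cells, was at 75.6 ± 8.11 and 76.4 ± 4.4 FPKM.

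Of 13 class I antigen presentation genes 2 rose and 2 fell, the same adjusted over the list alone (median -0.0478, adjusted p = 0.391). These were HLA-E (0.48), NLRC5, a transactivator of class I genes (0.43), HLA-B (-0.36) and ERAP1, a peptide-trimming protease (-0.34). Without CuB replicate 2 none of the 4 passed, at an adjusted p of 0.113, 0.0603, 0.145 and 0.078 in that order. HLA-E, HLA-B and ERAP1 also missed the threshold without DMSO replicate 3 (0.0986, 0.0819 and 0.0832) or CuB replicate 3 (0.0994, 0.092 and 0.0885), HLA-E and ERAP1 without DMSO replicate 1 (0.114 and 0.0984), and HLA-B without CuB replicate 1 (0.0667). HLA-E did not pass under the 4 rescalings (adjusted p from 0.0613 to 0.15), nor HLA-B without the variance trend (0.0507). With the replicate block HLA-B (0.0798) and ERAP1 (0.0651) did not pass, nor NLRC5 with the GC correction and the block (0.0599). HLA genes share sequence, so their fragments may be split between them. Of 14 interferon response genes 2 rose and 5 fell, the same adjusted over the list alone (median -0.0728, adjusted p = 0.285). IRF1 rose from 1.30 ± 0.019 to 12.3 ± 0.762 FPKM and IRF7 by 0.77 on the log2 scale, while BST2, which tethers virions, fell by 1.79 and OAS2, a sensor of double-stranded RNA, by 0.73.

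Inflammatory and growth-factor response genes had the 2 highest medians of the 30 tested lists. Of 28 immediate early genes 27 rose and MYC fell, the same adjusted over the list alone (median 2.90, adjusted p = 6.62e-19; adjusted p = 0.123 with an estimated correlation). All 18 tested NF-kB targets and inflammatory cytokines rose, also adjusted over the list alone (median 2.27, adjusted p = 4.36e-13; adjusted p = 0.119 with an estimated correlation). After TNFAIP3 and CXCL8 the largest were BIRC3, an inhibitor of apoptosis, from 3.33 ± 1.12 to 58.2 ± 12.1 FPKM, and CXCL2, a chemokine with close paralogs, from 2.69 ± 1.12 to 38.1 ± 8.13 FPKM. Of 20 genes of ERK pathway output 9 rose and 4 fell, the same adjusted over the list alone (median 0.182, adjusted p = 0.127; passed as higher with no filter on low values, adjusted p = 0.00715), with DUSP5, an ERK phosphatase, at 2.47, FOSL1 at 1.96 and IER3 at 1.63.

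Targets of SRF and MRTF and of YAP and TEAD rose as lists at the preset correlation, while the tubulins did not pass as a list. Of 20 targets of SRF and MRTF, which respond to actin assembly, 15 rose and 1 fell, the same adjusted over the list alone (median 1.34, adjusted p = 2.94e-07; adjusted p = 0.105 with an estimated correlation). ACTG1, cytoplasmic gamma actin, rose from 548.6 ± 41.5 to 2413 ± 31.8 FPKM, TPM1, a tropomyosin, from 3.31 ± 0.197 to 19.4 ± 0.532 FPKM, TUFT1 by 2.51 and FHL2 by 2.11 on the log2 scale. The member that fell was ACTA2, smooth muscle actin (-0.57), and actin genes are close in sequence. Of 21 YAP and TEAD targets 13 rose and 0 fell, or 15 and 0 adjusted over the list alone (median 0.759, adjusted p = 4.69e-05; adjusted p = 0.0853 with an estimated correlation). They included NUAK2, a kinase (1.07 ± 0.0443 to 22.5 ± 1.48 FPKM), GADD45A (2.98), ANKRD1 (1.89) and AXL, a receptor tyrosine kinase (1.45). Of 13 tubulins 7 rose and 3 fell, the same adjusted over the list alone (adjusted p = 0.195), with TUBB2A at 1.39, TUBE1 at 1.10, TUBB4A at -1.09 and TUBB2B, a close copy of TUBB2A, at 0.77.

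Markers of melanoma state were compared as well. Of 16 genes of the invasive state 9 rose and 3 fell, or 9 and 4 adjusted over the list alone (median 0.673, adjusted p = 0.0194; adjusted p = 0.135 with an estimated correlation; 0.0621 among genes of at least 5 FPKM). Beside JUN and FOSL1 they included NGFR, a neurotrophin receptor, from 3.03 ± 0.587 to 17.3 ± 3.82 FPKM, and FN1, fibronectin, from 15.3 ± 1.01 to 49.0 ± 1.59 FPKM. Of 7 tested melanocyte markers and MITF targets 2 rose and 2 fell, the same adjusted over the list alone (adjusted p = 0.547). BCL2A1, an anti-apoptotic BCL2 relative, rose by 2.38 and CDK2 by 0.62, while S100B went from 26.4 ± 1.61 to 6.64 ± 0.161 FPKM and ERBB3 from 63.9 ± 1.73 to 31.5 ± 0.782 FPKM. The median of this list was 0.124 and its mean 0.025 while the test pointed down, and the median was -0.0595 after quantile normalization and -0.00935 with equal fragment totals.

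Of 24 p53 targets 11 rose and 3 fell, the same adjusted over the list alone (median 0.348, adjusted p = 0.00417; adjusted p = 0.105 with an estimated correlation). SESN2, a stress-induced inhibitor of mTOR signalling, rose from 5.88 ± 0.802 to 83.2 ± 6.66 FPKM, GDF15, a stress cytokine, by 3.02 and BBC3, the BH3-only protein PUMA, by 2.35 on the log2 scale, and 10 members of this list are also in another list. Of 25 apoptosis regulators 11 rose and 0 fell, or 11 and 1 adjusted over the list alone (median 0.33, adjusted p = 0.000986; adjusted p = 0.105 with an estimated correlation). The 4 largest were the anti-apoptotic BIRC3 and BCL2A1 and the pro-apoptotic BBC3 and PMAIP1, the last from 17.9 ± 2.18 to 65.3 ± 9.78 FPKM. Of 17 autophagy genes 4 rose and 2 fell, or 5 and 2 adjusted over the list alone (adjusted p = 0.232), with SQSTM1, the cargo receptor p62, at 1.98, MAP1LC3B at 1.25 and GABARAPL1 at 0.65.

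Of 25 genes of DNA replication and G1/S 11 rose and 2 fell, or 12 and 2 adjusted over the list alone (median 0.364, adjusted p = 0.0117; adjusted p = 0.233 with an estimated correlation). MCM5, a subunit of the replicative helicase, rose by 1.03 and CDC45 by 0.61. This list did not pass after quantile normalization (adjusted p = 0.119) or among genes of at least 5 FPKM (0.0551). Of 28 genes of G2/M and mitosis 5 rose and 3 fell, the same adjusted over the list alone (adjusted p = 0.973). The median was 0.0274 and the mean 0.0386 while the test pointed down, and the median lay from -0.172 to -0.0401 under the 4 rescalings. CDC20, an activator of the anaphase-promoting complex, was at 0.81, KIF20A at -0.47 and CDC25C at -0.46. Only 5 of 16 replication-dependent histone genes were tested, and 4 rose, also adjusted over the list alone (median 0.679, adjusted p = 0.0406; adjusted p = 0.412 with an estimated correlation). HIST1H2AC rose from 2.15 ± 0.259 to 11.7 ± 2.62 FPKM and HIST1H2BK by 0.54 on the log2 scale, and histone genes are near-identical copies. Most of these mRNAs are known to lack a poly(A) tail, and why 11 genes fell below the filter was not tested. This call was lost without DMSO replicate 2 (adjusted p = 0.0963), CuB replicate 1 (0.0526) or CuB replicate 2 (0.068), with voom (0.0906), with the GC correction (0.123; 0.108 with the block) and among genes of at least 5 FPKM (0.0551).

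Cholesterol synthesis genes fell as a list at the preset correlation. Of 22 tested members 10 fell and 1 rose, or 11 and 1 adjusted over the list alone (median -0.353, adjusted p = 6.94e-06; adjusted p = 0.0853 with an estimated correlation). STARD4, a sterol carrier, went from 8.08 ± 1.17 to 1.73 ± 0.498 FPKM, SREBF2, the transcription factor of the pathway, from 30.6 ± 3.63 to 14.9 ± 0.486 FPKM, and DHCR7 fell by 0.95 on the log2 scale. Of 25 genes of hypoxia and glycolysis 9 rose and 2 fell, the same adjusted over the list alone, and the list did not pass (median 0.192 as deposited and -0.0304 after quantile normalization, adjusted p = 0.094). It passed as higher with no filter on low values, where 26 members were tested (adjusted p = 0.00813). VEGFA, an angiogenic growth factor, rose from 3.76 ± 0.575 to 15.9 ± 0.488 FPKM, SLC2A3 by 1.10 and the glucose transporter SLC2A1 by 0.70 on the log2 scale.

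The mitochondrially encoded mRNAs fell, with 8 of 13 down and 0 up, or 9 adjusted over the list alone (median -0.378, adjusted p = 0.000986; adjusted p = 0.308 with an estimated correlation). MT-CYB went from 2197 ± 218 to 1298 ± 131 FPKM and MT-ND4L fell by 0.69. The list did not pass after quantile normalization (adjusted p = 0.0679), where MT-ATP6 turned from -0.57 to 0.03. All genes of the mitochondrial chromosome, not only these mRNAs, made up 3.68 ± 0.371% of fragments with DMSO and 2.43 ± 0.239% with CuB. The 10 highest genes of each library took 4.92 ± 0.245% with DMSO and 4.28 ± 0.0855% with CuB. Both differences had an exact two-sided permutation p of 0.1, the smallest possible for 3 against 3, and 0.12 after adjustment over 6 library measures. Of 25 nuclear genes of oxidative phosphorylation 1 rose and 5 fell, or 0 and 4 adjusted over the list alone (median -0.0401, adjusted p = 0.134), with SDHC at -0.53. Of those that fell, NDUFB5, COX7A2 and NDUFA4 did not pass without CuB replicate 2 (adjusted p = 0.104, 0.0541 and 0.0527). The list passed as lower with libraries rescaled to the same sum (adjusted p = 0.0391), after quantile normalization (0.00399), with equal fragment totals (0.0175) and among genes of at least 5 FPKM (0.0254). Of 32 ribosomal protein genes 5 fell and 0 rose, or 0 and 0 adjusted over the list alone (median -0.0729, adjusted p = 0.0362; adjusted p = 0.466 with an estimated correlation). RPL7A was the largest, at -0.30. The call of this list was lost without DMSO replicate 2 (adjusted p = 0.236) or CuB replicate 2 (0.0774), without the variance trend (0.0719), with the replicate block (0.0728) and with no filter on low values (0.113).

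Markers of fibroblasts, immune cells and endothelium were low, while some epithelial markers were not. Of 12 keratinocyte and epithelial markers 6 were tested and 4 rose, or 5 adjusted over the list alone (median 0.5, adjusted p = 0.0643). The list passed without DMSO replicate 2 (adjusted p = 0.0258), after quantile normalization (0.0359), with equal fragment totals (0.0479) and with no filter on low values, where 11 members were tested (0.0294). KRT18, a simple-epithelium keratin that lies opposite KRT8, rose from 43.2 ± 2.65 to 74.9 ± 1.04 FPKM. The others that rose, KRT14, KRT10 and KRT8, did not pass without DMSO replicate 1 (adjusted p = 0.0873, 0.0698 and 0.0841) or DMSO replicate 3 (0.0955, 0.0572 and 0.075). They also missed the threshold without CuB replicate 2 (0.108, 0.0551 and 0.0831) or CuB replicate 3 (0.103, 0.0579 and 0.0808). Of 10 fibroblast, 12 immune and 8 endothelial markers, 1 each reached a mean of 1 FPKM, and these lists could not be tested as sets. PDGFRB, a fibroblast marker, went from 2.85 ± 0.395 to 1.29 ± 0.202 FPKM, and LYZ, an immune marker, from 1.66 ± 0.0589 to 0.794 ± 0.315 FPKM (adjusted p = 0.00382 and 0.0218, the same calls adjusted over the list alone). LYZ did not pass without DMSO replicate 1 (adjusted p = 0.0642), DMSO replicate 3 (0.0567), CuB replicate 1 (0.0522) or CuB replicate 2 (0.0736). ESAM, an endothelial marker, was at 1.12 ± 0.493 and 1.15 ± 0.223 FPKM (adjusted p = 0.88). The second most abundant marker of each, LUM, NKG7 and KDR, had a mean under 1 FPKM in both groups.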

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

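Equal fragment totals, voom on recovered fragments and the GC corrections were chosen after the data were seen; the other alternatives were set beforehand. Of the 156 named genes with alternatives, 119 kept their direction and their side of the threshold under every alternative fit in which they were tested, of 20 in all, 29 lost the threshold in at least 1, 5 gained it in at least 1 and 4 changed direction in at least 1. All calls shared with the main test kept their direction under each alternative (100%), which fits to the same libraries make nearly certain. Of the 5118 main calls, from 3179 (at least 5 FPKM) to 5085 (pseudocount of 0.5) were shared. The cause of a change was not tested except where stated.

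Gene counts moved by over 1.5 times under some settings. With a pseudocount of 0.1, 1525 genes changed at least 2-fold, 667 of them down, and 503 fell at least 2-fold with 0.5, since a smaller pseudocount shrinks low genes less. With at least 5 FPKM, fewer genes were tested and 3250 changed, 985 of them down; 594 changed at least 2-fold, 139 of them down. voom gave 1580 genes at least 2-fold, 694 of them down. Equal fragment totals gave 2022 up and 3128 down. The GC correction gave 7608 changed genes, 4016 up and 3592 down, against 5118, 3046 and 2072 in the main test. Of these counts only the falls moved by over 1.5 times. Leaving out 1 library gave from 3262 to 5755 changed genes, 1965 to 3443 up and 1297 to 2312 down, lowest without CuB replicate 2 and highest without DMSO replicate 2. Depths of 14845976 to 16137093 fragments leave wide intervals for genes with few fragments, such as MIR3125 with 27 and 1.

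With an estimated correlation 0 lists passed, and 0 with the GC correction added; the ATF4 list had an adjusted p of 0.0853 and 0.0697 and the STAT3 targets 0.135 and 0.253. fry, which does not compare with other genes, passed the chaperones (0.00236) and NRF2 targets (0.000245) and reversed the interferon list (0.15) and G2/M (0.553). Among lists not past the threshold, G2/M and melanocyte markers changed direction with no filter (0.451 for each), the chaperones with at least 5 FPKM (0.908) and quantile normalization (0.591), and the immunogenic cell death list with at least 5 FPKM (0.982), quantile normalization (0.949) and the GC correction with the replicate block (0.992). Without 1 library the adjusted p ran from 0.623 to 0.996 for the immunogenic cell death list and from 0.535 to 0.918 for G2/M, both with changes of direction.

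ESAM went to a log2 fold change of -0.0098 at the same sum, -0.0431 with equal fragment totals and -0.0045 with the GC correction, with or without the replicate block. HMGB1 went to -0.0825, -0.0494, -0.2246, -0.1441 and -0.0293 at the same sum, with median of ratios, quantile normalization, equal fragment totals and the GC correction, with or without the block. Without 1 library ESAM ran from -0.1348 to 0.2073, HMGB1 from -0.0693 to 0.0799 and CCPG1 from -0.1959 to 0.0083. MT-ATP6 went to 0.0301 under quantile normalization.

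With the replicate number as a block 4443 genes changed, against 5118 without it, and 4281 were shared. The correlations of deviations of same-numbered samples were 0.269, 0.118 and -0.357, which gave no sign of pairing by number. Not every sample correlated best with its own number, since DMSO 2 and CuB 3 reached 0.469 and DMSO 3 and CuB 1 reached 0.393. These samples were alike in GC trend. The deviations had a rho with GC of 0.774 and 0.648 in DMSO 2 and CuB 3, and of -0.703 and -0.667 in DMSO 3 and CuB 1. The check was not repeated after the GC correction, so it cannot tell whether the numbers pair the samples. With the GC correction and the block 7191 genes changed, 3787 up and 3404 down.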

Other observations

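The gene classes, the splits of the libraries, and the tests on list precision, GC content, gene length, depth and AU-rich elements were chosen after the results were seen; the tests on expression level and on decay factors were set before theirs. Classes of transcription factors moved in different directions with CuB. Of 26 tested HOX genes, which set positional identity, 19 fell and 1 rose (median -0.542, camera adjusted p = 1.27e-06 over 10 classes; adjusted p = 0.0678 with an estimated correlation). HOXB8 went from 9.23 ± 0.963 to 1.62 ± 0.149 FPKM (SD, n = 3) and HOXA5 from 11.4 ± 1.16 to 4.10 ± 0.547 FPKM, while HOXB9 rose from 15.1 ± 0.619 to 31.1 ± 1.15 FPKM. Of 13 Kruppel-like factors 9 rose and 1 fell (median 1.59, adjusted p = 1.09e-06; adjusted p = 0.0275 with an estimated correlation), with KLF2 from 1.71 ± 0.52 to 29.7 ± 2.51 FPKM, KLF5 from 10.3 ± 0.355 to 105.8 ± 14.4 FPKM and KLF4 at 2.81 on the log2 scale. Of 36 basic leucine zipper factors 25 rose and 2 fell (adjusted p = 1.11e-08; 0.0105 with an estimated correlation), a class that holds ATF3, JUN and DDIT3. Of 35 BTB zinc finger factors 18 rose and 3 fell (adjusted p = 0.00377; 0.0458 with an estimated correlation), and of 440 C2H2 zinc finger factors 199 rose and 31 fell (adjusted p = 1.03e-06; 0.131 with an estimated correlation). The medians of these classes kept their sign after the GC correction and at the same sum per library.

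Phosphatases and long noncoding RNAs moved as well. Of 16 dual specificity phosphatases, many of which switch off MAP kinases, 10 rose and 0 fell (median 0.618, adjusted p = 6.54e-05; 0.0275 with an estimated correlation), with DUSP1 from 6.59 ± 0.781 to 61.4 ± 1.43 FPKM and DUSP10 from 14.03 ± 1.33 to 71.2 ± 4.84 FPKM. Of 464 antisense genes 115 fell and 43 rose (median -0.22, adjusted p = 2.96e-05; 0.0103 with an estimated correlation), and of 448 lincRNA genes 131 fell and 59 rose (median -0.19, adjusted p = 0.000606; 0.0576 with an estimated correlation). The number of genes per library was 24662 ± 427.8 above 0 FPKM with CuB against 25352.7 ± 54.9 with DMSO, and 13017 ± 18.03 against 13462.3 ± 67.4 at 1 FPKM or more (exact two-sided permutation p = 0.1 for each, the smallest possible, and 0.12 after adjustment over 6 library measures). The kit does not mark strand, so fragments of antisense genes and their partners cannot be separated. Among 10865 protein-coding genes 2736 rose and 1653 fell (median 0.0803, and -0.00859 at the same sum per library; adjusted p = 0.00287; 0.0227 with an estimated correlation). The median log2 level was 1.43 for antisense, 1.55 for lincRNA, 3.22 for protein-coding and 3.97 for small nucleolar RNA host genes. Genes of at least 5 FPKM had a median log2 fold change of 0.127, against 0.0548 for all tested genes. The classes were not matched on level, so class and level were not separated. Of 20 small nucleolar RNA host genes 10 rose and 2 fell (median 0.521, adjusted p = 0.00616; 0.0678 with an estimated correlation). This class was taken by name and is not separate from the antisense genes, which also hold SNHG12. SNHG12 was at 1.95, SNHG1 at 1.41 and GAS5 at 0.99 on the log2 scale. Such host transcripts are known targets of nonsense-mediated decay, so release of that pathway may contribute. The 7 decay factors whose own mRNAs are targets had a median of 0.439, with 5 up and 0 down, SMG1 at 0.73 and SMG5 at 0.53. The bound set for release was 0.5, and the median lay at percentile 94.1 of random lists matched on level, so this test left the hypothesis open.

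The rise of the ATF4 list was set against the XBP1 and chaperone lists. The mean shift had a 95% interval of -0.256 to 0.189 for XBP1 targets and 0.0244 to 0.213 for chaperones. A hidden mean rise of the size of the bound of 1 was thus argued against by precision. That bound was set after the list results were seen, and smaller rises are not argued against. The chaperone interval lay above 0, so a small mean rise was measured as deposited. Level did not account for the rise of the ATF4 list. Of 10000 random lists matched on level, 0 had a mean shift as high as 2.39 (highest random list 0.591). The ATF4 list exceeded the XBP1 targets by 2.41 after the GC correction (95% interval 2.31 to 2.51). The biological explanation stays open, since 6 h is a single time and XBP1 splicing was not analysed here.

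The libraries of each group spread along the second principal component, which held 15.6% of the variance beside 71.1% for the first. Its gene loadings followed transcript GC content across genes (rho 0.791), which is consistent with a GC effect of library preparation, and gene length far less (rho -0.131); genes are not independent replicates. The order of fragment totals matched the order on this component in 1 of 2 groups, so depth and another source cannot be told apart with 3 libraries a group. The log2 fold changes between groups were nearly unrelated to GC (rho 0.029). No biological explanation was tested, since the design names no factor within a group.

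Immediate early and NF-kB genes rose together. The mean shift of both lists joined, 2.73, was reached by 0 of 10000 random lists matched on level (highest random list 0.466). General stabilisation of mRNAs with AU-rich elements would raise other carriers as well. Carriers of an AU-rich nonamer in the 3' UTR, list members included, shifted by 0.0756 more than other genes at matched UTR length. The 95% interval of 0.0427 to 0.107 lay below the bound of 0.25 (permutation p = 1e-04, the smallest 10000 permutations can give). This interval and this p treat genes as replicates, so they do not measure the spread between libraries. The shift was not recomputed after the GC correction or without the list members. Of 46 list members with an annotated 3' UTR 17 (37%) carried a nonamer against 22.6% of all genes, and members with one had a median log2 fold change of 3.05 against 2.55 for members without one, a difference that was not tested. A stabilisation restricted to these genes, or transcription driven by the treatment, may account for the rise, and neither was tested.

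The 6 libraries can be split into 3 and 3 in 10 ways, which cannot give a share under 0.05. The real split was the 1 of 10 with as many changed genes (5118, highest other 0), the 1 of 10 with as many genes at least 2-fold (961, highest other 0), and the 1 of 10 with as many lists past the threshold (16, highest other 13). These counts are from limma. The other splits gave from 4 to 13 lists at the preset correlation. Each of them sets 2 libraries of one group and 1 of the other on each side. The treatment difference then lies within both sides and widens the spread. Their gene counts of 0 therefore do not show what chance alone would give. A remaining part of the treatment difference, correlation between genes or a structure of the samples may give such list calls, and these were not separated. At an unadjusted p under 0.05 the other splits gave from 80 to 2149 genes, against 6422 for the real split. The highest was for DMSO 1, DMSO 3 and CuB 1 against the rest, the 3 libraries lowest on the second component.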
